A study of Rattus norvegicus with 12 samples.

How the data were processed

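Polyadenylated RNA was measured in 12 libraries of rat cells labelled as primary hepatic stellate cells, 4 per group, after 24 h of co-culture through Transwell inserts with hAEC, with hAMSC or with vehicle. Per the labels' protocols, RNA was extracted with the RNAqueous-Micro kit and libraries were made with the TruSeq stranded mRNA kit. The deposited values are expected counts per gene, as RSEM estimates them. Per the submitters' processing notes, FastQC, Trim Galore, STAR, RSEM and limma were used, with the builds rn6 and Rnor_6.0; versions and the roles of the tools are not given in the sources used here. Of the deposited expected counts, zeros included, 90.1% were whole numbers, so the share among values above 0 was lower. RSEM shares a read that fits several genes among them, so close paralogs, pseudogenes and overlapping genes carry a further uncertainty that the tests do not hold. The files list 32623 genes, of which 12070 had 0 in all libraries. Gene symbols are those that the files pair with the Ensembl identifiers, and 197 genes had none. No genome of the build was used here, so no coordinates are given.

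Total counts ran from 27382724 to 34922211 per library. Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3: the default expression filter (filterByExpr) kept 13539 genes, libraries were scaled with TMM (factors 0.973 to 1.03), and the robust quasi-likelihood fit (glmQLFit, glmQLFTest) was made over all 12 libraries in 1 model, with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM were computed from these counts. The group was the only term in the planned model. Sample numbers are not shared between groups, so no pairing was used. No libraries were duplicates: counts of every pair differed by more than sampling noise. The labels do not say whether the libraries of a group came from separate rats or cultures, so p-values measure only the spread between these libraries, which may be technical.

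The comparisons were hAEC against vehicle, hAMSC against vehicle and hAEC against hAMSC, all two-sided. The tests, the gene lists, the rule for named genes and the other settings to be tried were chosen before the data were examined. The rule names, for each co-culture against vehicle, the 10 largest rises and 10 largest falls among genes that passed, with a mean of at least 5 CPM and a symbol that is not provisional, and 5 in each direction for hAEC against hAMSC. Where no gene passed, it names the 5 genes in each direction with the smallest p, as not passing. It always names Acta2, Col1a1, Col1a2, Col3a1, Timp1, Mmp2, Tgfb1, Pdgfrb, Des, Lrat and Pparg, and for each list up to 3 members with the smallest p. Some genes that the rule names are not reported here. The rule was applied again, unchanged, to the fits with the library set.

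The 15 process lists covered extracellular matrix, contractile and myofibroblast genes, stellate cell quiescence, matrix turnover, TGF-beta signalling, inflammatory cytokines and NF-kB targets, interferon response, cell cycle, hypoxia and glycolysis, cholesterol biosynthesis, unfolded protein and amino acid response, NRF2 antioxidant genes, immediate early and heat shock genes, vasoactive genes and p53 targets. The 8 marker lists covered hepatocytes, macrophages, endothelium, epithelium and cholangiocytes, lymphocytes, neutrophils, mesothelium and portal fibroblasts, and erythroid cells. Col1a2 and Pecam1 were not analysed here. Lists were tested with camera (limma 3.58.1) on voom values with a preset correlation of 0.01, which compares a list with the other genes, and again with an estimated correlation and with fry, which tests whether a list's genes move on balance one way. None of the calls by camera held with an estimated correlation. For some lists that did not pass, such as TGF-beta signalling, macrophage markers and the unfolded protein list, the direction of camera differed from the sign of the list's median or mean; for lists that passed, these did not differ in sign. Marker levels, as the mean log2 CPM of a list's members, were compared by exact permutation over the 70 arrangements of 8 libraries, and, after the data were seen, over the 36 that exchange libraries only within a library set.

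Principal components of the 2000 most variable genes parted the libraries into 2 sets, which cross the groups and are not named by the labels. After the data were seen, the fit was therefore repeated with the set as a term, within each set alone, and with the endothelial marker level as a further covariate, and the direction of genes called within one set was read in the other. The other settings chosen beforehand were scaling by relative log expression, by upper quartile or by library size alone, no expression filter, a mean of at least 5 CPM, DESeq2 1.42.0, limma voom with and without quality weights, a fit that is not robust, the 2 groups alone, the sample number range as a covariate, 1 surrogate variable from sva 3.50.0, and leaving out each library in turn. Other splits of the 8 libraries of a comparison were counted, and correlations between the co-cultures were set beside 20 simulations of unchanged groups and beside split vehicle libraries. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

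The edgeR fits were tested on simulated data for hAMSC against vehicle, drawn for 13539 genes from the means and spread of these libraries. The expression filter was applied again and kept 13405 of them. With the set in the model, the fit recovered 23.9% of 67 genes changed by a fold of 1.2, 61.2% of 67 genes at 1.5 and 83.1% of 65 genes at 2. With the group alone it recovered 0, 17.9% and 49.2%. Over 12 draws, 78 of 1493 calls with the set (5.22%) were of unchanged genes, against 218 of 1752 (12.4%) for DESeq2 and 89 of 1402 (6.35%) for limma voom.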

Results

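The series measured polyadenylated RNA in rat cells labelled as primary hepatic stellate cells, the vitamin A storing pericytes of the liver sinusoid that turn into collagen-producing myofibroblasts in fibrosis. The cells had been isolated by gradient centrifugation from rats made cirrhotic by chronic inhalation of carbon tetrachloride. They were then kept for 24 h with Transwell inserts, porous cups that pass soluble products but not cells, which held 15000 viable human amniotic epithelial cells (hAEC), 15000 viable human amniotic mesenchymal stromal cells (hAMSC) or vehicle. Each of the 3 groups had 4 libraries, named here by the sample numbers of the labels: hAEC 3, 4, 11 and 12, hAMSC 7, 8, 15 and 16, and vehicle 17, 18, 19 and 20. Total counts ran from 27382724 in vehicle 17 to 34922211 in hAMSC 7, and 16167 to 16721 genes had a count in a library. The 10 most abundant genes held 8.77% to 11.8% of a library's counts, and mitochondrial genes held 1.73% to 2.61%. The series is about cell therapy of cirrhosis and portal hypertension, and the comparisons ask whether the rat cells responded to either human cell type and whether the 2 responses differed.

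Genes of macrophages were among the most abundant transcripts in every group. Gpnmb, a lysosomal glycoprotein of phagocytes, averaged 20180 CPM (a counts-per-million unit) over the 12 libraries, and Cd74, the invariant chain of antigen presentation, 8188 CPM. The lysosomal proteases Ctsb and Ctsd averaged 8098 and 6850 CPM, lysozyme Lyz2 5008 CPM, and the macrophage elastase Mmp12 4954 CPM. All 17 macrophage markers were measured, with a median of 584 CPM, and 14 of them were above 100 CPM. Cd68, a lysosomal protein of macrophages, lay between 1568 and 1664 CPM, and Clec4f, a lectin of liver macrophages, between 725 and 1041 CPM. Genes of stellate cells and myofibroblasts were near the lower end of measurement: Acta2, the smooth muscle actin of activated stellate cells, averaged 1.87 CPM, Col1a1 2.19 CPM and Col3a1 1.52 CPM. Lrat, which makes the retinyl esters stored by quiescent stellate cells, was between 0 and 0.368 CPM. The median member of the extracellular matrix list was at 1.64 CPM (32 members in the files, of which 28 were tested), that of the contractile list at 3.11 CPM (19 members, 14 tested) and that of the quiescence list at 0.637 CPM (19 members, 10 tested). In each library the macrophage list median exceeded the median of the 28 tested matrix genes, by a factor of 253 in vehicle 17 to 431 in hAMSC 7. Endothelial markers had a median of 19.5 CPM, and the medians of the hepatocyte (0.258 CPM), lymphocyte (0.523 CPM), neutrophil (0.153 CPM) and mesothelial and portal fibroblast (0.466 CPM) lists were below 1 CPM, as was that of the epithelial list (0.49 CPM). No erythroid marker reached the count needed for testing (median 0.00499 CPM). This composition stands beside every result that follows.

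**Figure D1:**
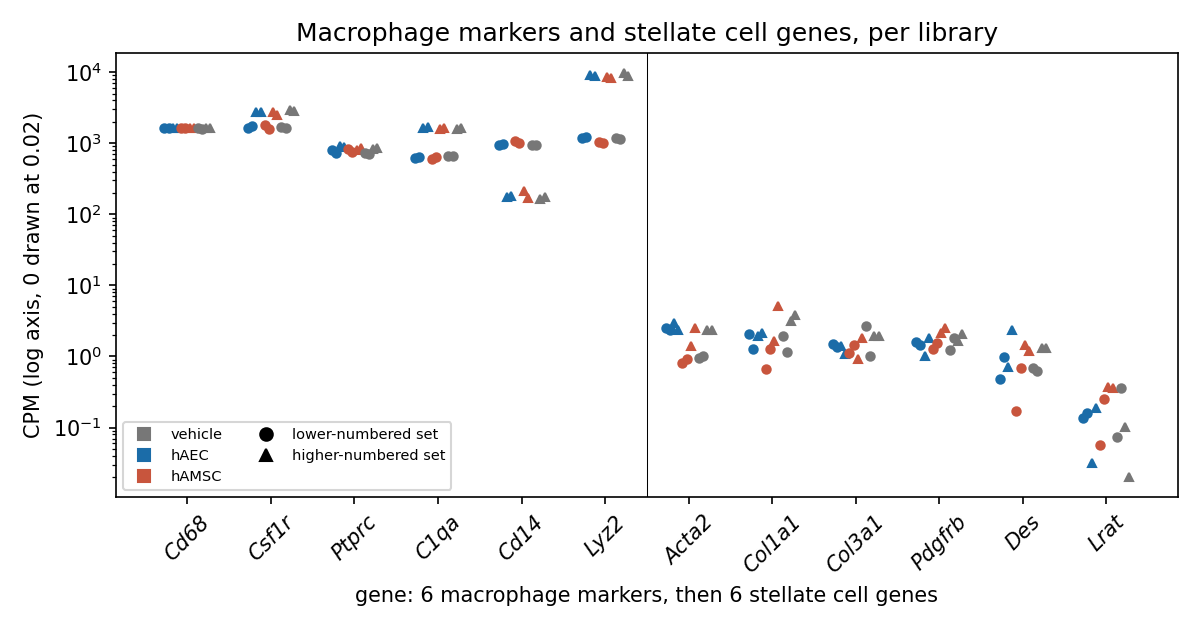
CPM (vertical log axis, 0 drawn at the foot) of 6 macrophage markers and 6 stellate cell genes, with a point for each of the 12 libraries, coloured by group and shaped by library set. Cd68 lies between 1568 and 1664 CPM in all libraries, and Lrat between 0 and 0.368 CPM.

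Over all 4 libraries of a group, no difference in macrophage marker level between the groups was detected. Its mean log2 CPM was 8.37 ± 0.50 (SD, n = 4) with hAEC, 8.37 ± 0.52 with hAMSC and 8.38 ± 0.44 with vehicle. Hepatocyte markers were 0.60 log2 units lower with hAMSC than with vehicle (difference -0.60, two-sided exact permutation p = 0.114), and endothelial markers differed by -0.58 between hAEC and hAMSC (exact permutation p = 0.171). All 21 exact permutation tests of marker levels gave an adjusted p of 1. The smallest p that 4 against 4 libraries allow is 0.0286. These tests leave out the 2 sets into which the libraries fell. With libraries exchanged only within a set, chosen after the data were seen, both of these differences gave an exact permutation p of 0.0556, the smallest that the 36 arrangements allow (adjusted p = 0.583). Within each set every hAMSC library lay below every vehicle library in hepatocyte markers, and every hAEC library below every hAMSC library in endothelial markers.

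The libraries fell into 2 sets that cross the groups, and 7 of the 17 macrophage markers were over 1 log2 unit higher in one set and 2 in the other. In libraries 11, 12, 15, 16, 19 and 20, the higher-numbered set, the apolipoprotein gene Apoe lay between 4408 and 5963 CPM, against 94.4 to 128 CPM in libraries 3, 4, 7, 8, 17 and 18, the lower-numbered set. The scavenger receptor gene Stab1 (1090 to 1447 against 27.4 to 36.7 CPM) and the complement gene C3 (192 to 242 against 13.4 to 15.6 CPM) were likewise higher in the higher-numbered set, as were the resident macrophage receptor gene Adgre1 (735 to 787 against 58.2 to 76.6 CPM) and Lyz2 (8315 to 9668 against 1001 to 1210 CPM). The inflammatory cytokine gene Il1b was higher in the lower-numbered set, at 645 to 732 against 39.6 to 49.8 CPM, as were the chemokine genes Cxcl3 (400 to 483 against 5.08 to 9.04 CPM) and Ccl9 (1884 to 2116 against 110 to 118 CPM). So was the endotoxin co-receptor gene Cd14 (947 to 1079 against 162 to 216 CPM). The first principal component held 73.5% of the variance of the 2000 most variable genes and parted the sets, and the second held 4.72%. Spearman's rho between libraries, across genes, which are not independent replicates, was 0.993 to 0.996 within a set and 0.939 to 0.951 between sets, and libraries of a group that lay in different sets had the same range of 0.939 to 0.951. Each set held 2 libraries of each group, so the set was not confounded with treatment. With the group alone in the model the biological coefficient of variation was 38.9%, and with the set added it was 9.92%. The sets were seen in the data and are not given by the labels, so every fit with the set in the model was chosen after the data were seen.

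**Figure D2:**
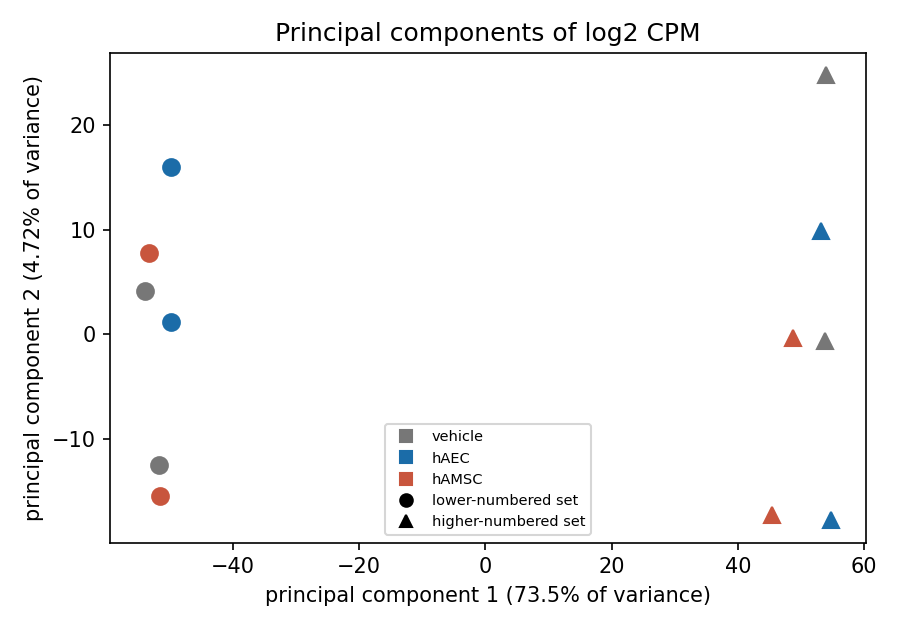
First principal component (horizontal, 73.5% of variance) against second (vertical, 4.72%) of log2 CPM, with a point for each of the 12 libraries, coloured by group and shaped by set. The first component parts the 6 lower-numbered from the 6 higher-numbered libraries, and each set holds 2 libraries of each group.

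Stellate cell genes were low in all groups, and none of those fixed for reporting passed a test over all genes. Acta2 was at 2.55 ± 0.303 CPM (SD, n = 4) with hAEC, 1.41 ± 0.794 with hAMSC and 1.68 ± 0.819 with vehicle. Col1a1 was at 1.85 ± 0.403, 2.20 ± 2.05 and 2.55 ± 1.26 CPM and Col3a1, another fibrillar collagen, at 1.33 ± 0.179, 1.33 ± 0.389 and 1.91 ± 0.686 CPM in the same order. Timp1, which inhibits matrix proteases, was at 23.4 ± 16.7, 24.0 ± 18.02 and 25.8 ± 17.8 CPM, and Tgfb1, the profibrotic growth factor, at 260 ± 20.1, 249 ± 5.69 and 260 ± 19.4 CPM. The log2 fold changes for hAEC and hAMSC against vehicle were -0.14 and -0.28 for the gelatinase Mmp2, -0.22 and 0.13 for the platelet-derived growth factor receptor Pdgfrb, and 0.20 and -0.18 for desmin (Des). They were -0.08 and -0.09 for Pparg, a nuclear receptor of quiescent stellate cells. The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment gave an adjusted p of 1 for each of these genes in all 3 comparisons. With the library set in the model, Acta2 had a log2 difference of 0.98 (SE 0.25) between hAEC and hAMSC, 1.495 within the lower-numbered and 0.46 within the higher-numbered set. It did not pass over all genes (edgeR quasi-likelihood with Benjamini-Hochberg, adjusted p = 0.239) and passed when adjusted over the list alone. Col1a2 was not analysed here.

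The 6 lists of stellate cell biology did not pass the list test in any comparison, with or without the library set. With the set in the model the matrix list had 7 of 28 members above 0 with hAEC (camera with Benjamini-Hochberg, adjusted p = 0.143) and 8 of 28 with hAMSC (adjusted p = 0.224). The contractile list gave 0.972 and 0.724 in the same order by camera with Benjamini-Hochberg, the quiescence list 0.818 and 0.724, the matrix turnover list 0.567 and 0.957, the TGF-beta signalling list 0.515 and 0.762, and the vasoactive list 0.652 and 0.724. Adjusted over the list alone with the set in the model, the growth factor gene Hgf (log2 0.23) and the TGF-beta receptor gene Tgfbr1 (0.25) rose with hAEC. With hAMSC, likewise over the list alone, the co-receptor gene Tgfbr3 (0.76), the lipid droplet gene Plin2 (0.17), the endothelin-converting enzyme gene Ece1 (0.15) and the adenosine receptor gene Adora2a (0.32) rose, the LIM-domain gene Csrp1 (0.16) rose, and the matrix protein gene Tgfbi fell (-0.28). The direction of the test for the contractile list with hAEC was down while the list median was above 0 (0.03).

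For hAEC against vehicle, no gene passed, and the clearest group was the cholesterol biosynthesis list. Of its 23 measured members 21 had a positive log2 fold change, with a median of 0.10, and the list rose (camera with Benjamini-Hochberg, adjusted p = 0.0256; adjusted p = 0.956 with an estimated correlation). Hsd17b7 (0.19), Insig1 (0.10) and Sqle (0.16), which act in or control sterol synthesis, had its smallest p-values, none of which passed. The 21 other lists tested did not pass, the nearest being cell cycle genes and endothelial markers, each at an adjusted p of 0.161. Among single genes, C1galt1, a mucin-type glycosylation enzyme, was at 42.5 ± 3.36 CPM (SD, n = 4) with hAEC and 32.8 ± 0.168 with vehicle (log2 0.38). Rngtt (0.23), the mitochondrial complex I gene Mt-nd4l (1.17), Prdm10 (0.20) and Zfp347 (0.71) were the next highest by p. Mocs1 (-0.16), Spopl (-0.18), Commd5 (-0.20), Tmco3 (-0.64) and Rad54l2 (-0.23) had the smallest p-values among genes that were lower. These 10 genes did not pass, with an adjusted p of 1 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. That test called 0 of 13539 genes, with 107 at an unadjusted p under 0.05. Chance gives 677 only where the residual spread is that of like libraries. Here it also held the difference between the library sets (biological coefficient of variation 38.9%, and 9.92% with the set in the model). Fewer than 677 are therefore expected with no effect, and the low count does not show that nothing changed. Limma voom called 0 and DESeq2 called 1, LOC103694380, named after its value was seen. The cholesterol call was lost without hAEC 11 (adjusted p = 0.738), hAEC 12 (0.941), vehicle 17 (0.687) or vehicle 18 (0.77), and with sample quality weights (0.912); the list median on camera's scale ran from -0.01 without vehicle 18 to 0.20 without vehicle 20. The number of lists called was 6 without hAEC 3, 6 without hAEC 4, 0 without hAEC 11, 0 without vehicle 17, 0 without vehicle 18, 4 without vehicle 19 and 5 without vehicle 20. In these fits 1 group held 2 libraries of one set and 1 of the other, with the set not in the model. The cholesterol list lay at 4.785 to 4.928 log2 CPM in the lower-numbered libraries and 5.478 to 5.643 in the higher-numbered ones. This imbalance by itself moves the list median, so these losses do not show that the call hung on single libraries.

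With the library set in the model, the cholesterol list again rose with hAEC, and 5 further lists passed. Of the 23 cholesterol genes 8 rose when adjusted over the list alone, among them Hmgcs1, Sqle, Idi1, Cyp51, Msmo1 and Sc5d, and 0 when adjusted over all genes. The sterol demethylase Cyp51 rose by 0.19 (SE 0.04) and the isomerase Idi1 by 0.25 (SE 0.09) on the log2 scale. By camera with Benjamini-Hochberg this list had an adjusted p of 1.29e-09, and an adjusted p of 0.0888 with an estimated correlation. By fry with Benjamini-Hochberg its adjusted p was 0.035. By camera with the preset correlation it passed in every fit that left out 1 library. The NF-kB target list fell (adjusted p = 0.000609; adjusted p = 0.66 with an estimated correlation), with 7 of 29 members above 0 and the chemokine genes Cxcl2 (-0.29), Ccl3 (-0.15) and Ccl4 (-0.18) as its members of smallest p. Endothelial markers fell (adjusted p = 0.00125; adjusted p = 0.66 with an estimated correlation) and cell cycle genes rose with 22 of 29 members above 0 (adjusted p = 0.00154; adjusted p = 0.66 with an estimated correlation). Hypoxia and glycolysis genes fell (adjusted p = 0.0265; adjusted p = 0.66 with an estimated correlation). No member of these 3 lists or of the NF-kB list passed over the list alone. NRF2 antioxidant genes fell (adjusted p = 0.00795; adjusted p = 0.66 with an estimated correlation), where the quinone reductase gene Nqo1 (-0.15) fell over the list alone. Of the other 16 lists, immediate early genes and mesothelial markers were nearest (both 0.112), and macrophage (0.242), p53 (0.49), neutrophil (0.49), hepatocyte (0.567), epithelial (0.567), interferon (0.719), unfolded protein (0.972) and lymphocyte (0.972) lists did not pass. Among single genes the calcium channel gene Trpc6 (0.34, SE 0.06) had the smallest adjusted p by edgeR quasi-likelihood with Benjamini-Hochberg (0.394), followed by Cyp51 and Ptprn (-0.49), both at 0.53. This test called 0 genes, and 759 were at an unadjusted p under 0.05, where 677 are expected by chance. Fitted on the 2 groups alone, it called 10 genes (8 higher, 2 lower). Limma voom called 0 and DESeq2 2, Trpc6 and Cyp51. Etv1 (0.29), Fads1 (0.30), Cbfb (0.25), Pc (-0.16), Map1a (-0.25), Mocs1 (-0.16) and Nqo1 (-0.15) completed the 5 genes of smallest p in each direction that the rule names, and did not pass. The cell cycle call was lost without vehicle 20 (adjusted p = 0.107), the NRF2 call without vehicle 19 (0.081), the endothelial call without vehicle 18 (0.0726). The hypoxia call was lost without hAEC 3 (0.129), hAEC 11 (0.0687), vehicle 17 (0.274) or vehicle 19 (0.081). Within the sets, which leave 2 libraries against 2, the lower-numbered set called 1 gene, Ms4a6e, and the higher-numbered set 6. Ms4a6e had the same direction in the other set. Of the 6, 5 were measured in the lower-numbered set and 1 had the same direction there.

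For hAMSC against vehicle with the group alone in the model, the macrophage scavenger receptor gene Cd163, which clears haemoglobin bound to haptoglobin, had the largest difference among the genes of smallest p that were higher. It was at 144 ± 23.9 CPM (SD, n = 4) with hAMSC and 94.3 ± 10.9 with vehicle (log2 0.61), followed by Mcoln3 (0.28), the phospholipase gene Pla2g4a (0.22), the sterol sensor Insig1 (0.19) and Atp8b4 (0.22). Among lower genes, haem oxygenase Hmox1 was at 2319 ± 162 against 2667 ± 52.6 CPM (-0.20), beside Arhgef40 (-0.27), Ogfr (-0.16) and Klhl21 (-0.18). All had an adjusted p of 1 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, which called 0 genes, with 142 at an unadjusted p under 0.05; limma voom and DESeq2 called 0 each. The cholesterol list rose with 21 of 23 members above 0 and a median of 0.15 (camera with Benjamini-Hochberg, adjusted p = 0.00193; adjusted p = 0.745 with an estimated correlation). Endothelial markers rose (adjusted p = 0.037; adjusted p = 0.656 with an estimated correlation). NRF2 antioxidant genes fell (adjusted p = 0.00381; adjusted p = 0.262 with an estimated correlation). Hepatocyte markers fell, with a median of -0.72 over 7 members (adjusted p = 0.00431; adjusted p = 0.438 with an estimated correlation). The matrix list (0.054), cell cycle genes (0.0686) and the 16 other lists tested did not pass. The cholesterol call was lost without hAMSC 15 (adjusted p = 0.631), hAMSC 16 (0.526), vehicle 17 (0.327) or vehicle 18 (0.585), its median on camera's scale running from -0.01 without hAMSC 15 to 0.22 without hAMSC 8, and the NRF2 call without hAMSC 15 (0.0619), hAMSC 16 (0.0857) or vehicle 17 (0.183). With sample quality weights the cholesterol (adjusted p = 0.798, median -0.02), NRF2 (0.0782) and endothelial (0.21) calls were lost, and with a mean of at least 5 CPM the endothelial call (0.406). The hepatocyte call was lost without hAMSC 7 (0.145; median on camera's scale from -0.85 to -0.55), hAMSC 16 (0.0568) or vehicle 17 (0.183). The endothelial median on that scale, 0.18 with all libraries, ran from 0.05 without vehicle 20 to 0.51 without vehicle 17, and the call was lost without hAMSC 7 (0.0525), 8 (0.123), 15 (0.145) or 16 (0.0568) or vehicle 19 (0.39) or 20 (0.363). The number of lists called, 4 with all libraries, was 11 without hAMSC 8, 1 without hAMSC 15, 0 without hAMSC 16, 1 without vehicle 17, 7 without vehicle 19 and 8 without vehicle 20. As for hAEC, these fits left the sets unequal in 1 group. For lists whose level differs between the sets, that imbalance and the library left out cannot be told apart.

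With the library set in the model, 32 genes changed with hAMSC against vehicle, 21 higher and 11 lower. Cd163 (ENSRNOG00000010253) rose by 52.7% (log2 0.61, SE 0.09; 0.55 within the lower-numbered and 0.68 within the higher-numbered set; adjusted p = 0.0277 by edgeR quasi-likelihood with Benjamini-Hochberg). The inhibitory immune ligand gene Cd200 rose by 41.0% (log2 0.50, SE 0.07; sets 0.38 and 0.63; adjusted p = 0.00496), and the gene of its receptor, Cd200r1, by 31.1% (log2 0.39; sets 0.45 and 0.33; adjusted p = 0.0277). The proteoglycan gene Vcan (ENSRNOG00000029212) rose by 37.6% (log2 0.46; adjusted p = 0.00496), the prohormone convertase gene Pcsk1 (ENSRNOG00000011107) by 31.3% (log2 0.39; adjusted p = 0.00173) and the chemokine gene Ccl6 by 31.9% (log2 0.40; adjusted p = 0.0277). The NAD-consuming enzyme gene Cd38 (0.40), the guanine deaminase gene Gda (0.38), Tspan7 (0.38) and the fatty acid desaturase gene Fads1 (0.37) completed the 10 largest rises. The largest fall was that of Fcrl2, an Fc receptor-like gene, with a log2 change of -0.58 (SE 0.07; adjusted p = 0.00196), where the lower-numbered libraries lay between 0.469 and 0.992 CPM and the higher-numbered ones between 160 and 237 CPM. The glutathione transferase genes Gstp1 (-0.28, SE 0.03; adjusted p = 0.00196) and Gsta1 (-0.23) and the quinone reductase gene Nqo1 (-0.27, SE 0.04; adjusted p = 0.00648) also fell. Tsen34l1 (-0.48), the scaffold gene Slc9a3r2 (-0.40), the pyruvate carboxylase gene Pc (-0.27), the stress gene Sesn2 (-0.25), the mitophagy kinase gene Pink1 (-0.24) and the autophagy kinase gene Ulk1 (-0.24) completed the 10 largest falls. All 32 had the same direction within both sets, whose libraries had taken part in the calls. Of the genes called within the lower-numbered set alone, 50 of 86 had the same direction in the higher-numbered set (39 of 66 rises, 11 of 20 falls). Of those called within the higher-numbered set alone, 55 of 92 measured had the same direction in the lower-numbered one (40 of 75 rises, 15 of 17 falls). Chance alone gives about as many genes in the same direction as in the opposite one. These adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 13539 genes. Of the 13539, 1310 were at an unadjusted p under 0.05, where 677 are expected by chance. Limma voom called 25 and DESeq2 155. By edgeR, a fit that is not robust called 12 and the 2 groups alone gave 9. Within the lower-numbered set alone 86 genes were called and within the higher-numbered set 94, with 4 in both (Cd200, Pcsk1, Gstp1 and Rnd1). Rnd1, a small GTPase gene named after its values were seen, went in opposite directions, at 31.6 against 43.5 CPM in vehicle in the lower-numbered set and 10.3 against 3.91 CPM in the higher-numbered one. The count was 56 without hAMSC 7 (28 of the 32 among them), 13 without hAMSC 8 (11), 153 without hAMSC 15 (32) and 9 without hAMSC 16 (9). It was 21 without vehicle 17 (17 of the 32 among them), 8 without vehicle 18 (8), 12 without vehicle 19 (11) and 11 without vehicle 20 (11). In hAMSC 15 and 16 the endothelial marker level was 3.75 and 3.49 log2 CPM, against 2.92 and 2.84 in vehicle 19 and 20, while hAMSC 7 and 8 (3.97 and 4.204) lay near vehicle 17 and 18 (4.09 and 4.14). With that level as a further covariate 93 genes were called, 17 of the 32 among them.

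**Figure D3:**
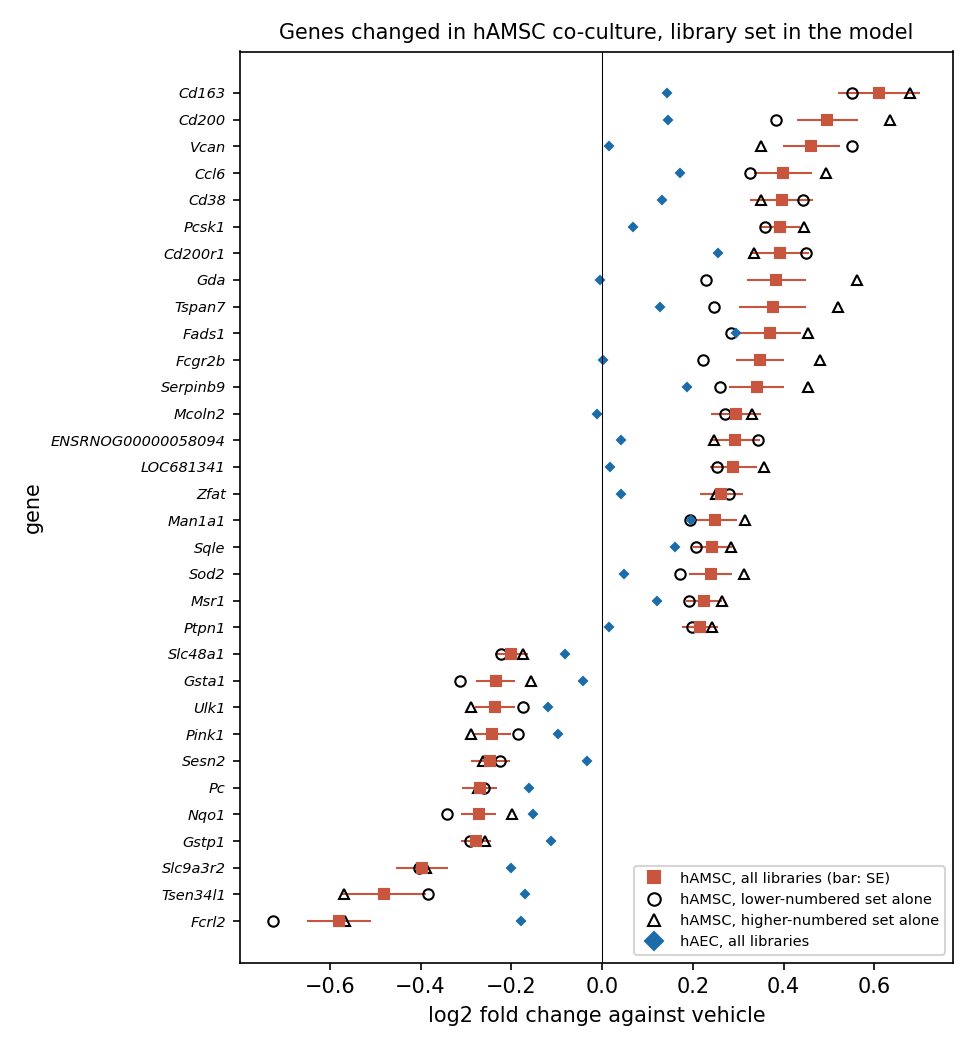
Log2 fold change against vehicle (horizontal) of the 32 genes that changed with hAMSC with the library set in the model, as squares with SE bars, beside the values within each set (open symbols) and those for hAEC (diamonds). Cd163 is highest at 0.61 and Fcrl2 lowest at -0.58, and the open symbols lie on the side of the square for all 32 genes.

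Among the lists, cholesterol biosynthesis rose with hAMSC and NRF2 antioxidant genes fell, with the library set in the model. Of 23 cholesterol genes 20 were above 0, 10 rose when adjusted over the list alone and 1, the squalene epoxidase gene Sqle, over all genes (log2 0.24, SE 0.04; adjusted p = 0.0277 by edgeR quasi-likelihood with Benjamini-Hochberg). Cyp51 rose by 0.17 and Insig1 by 0.19 on the log2 scale over the list alone. The list had an adjusted p of 1.3e-10 by camera with Benjamini-Hochberg, an adjusted p of 0.0626 with an estimated correlation, and passed in every fit that left out 1 library. Of 14 NRF2 genes 12 were below 0, and Nqo1, Hmox1 (-0.20), Gclm (-0.17), Osgin1 and Tkt fell over the list alone while the cystine transporter gene Slc7a11 (0.40) rose (adjusted p = 9.89e-05 by camera; adjusted p = 0.232 with an estimated correlation). Cell cycle genes rose, with 27 of 29 above 0 and the topoisomerase gene Top2a at 0.42, and none passing singly (adjusted p = 0.000232; adjusted p = 0.469 with an estimated correlation). The p53 target list fell, with the kinase gene Plk2 (-0.18) falling over the list alone (adjusted p = 0.00073; adjusted p = 0.214 with an estimated correlation). The unfolded protein and amino acid list fell (adjusted p = 0.0298; adjusted p = 0.469 with an estimated correlation), and its members divided. Over the list alone 8 fell, among them the transcription factor gene Atf4 (-0.14) and the amino acid enzyme genes Asns (-0.17), Phgdh (-0.27) and Chac1 (-0.41), while the chaperone genes Hspa5 (0.10), Dnajb9 (0.24) and Creld2 (0.27) rose. Immediate early genes fell (adjusted p = 0.0316; adjusted p = 0.567 with an estimated correlation), with Fosl1 (-0.46) falling over the list alone. Hepatocyte (0.0918), neutrophil (0.181), hypoxia (0.33), NF-kB (0.338), endothelial (0.338), mesothelial (0.338), lymphocyte (0.404), interferon (0.617), macrophage (0.801) and epithelial (0.801) lists did not pass. Over the list alone the macrophage markers Cd163 and Cd14 (0.17) and the endothelial receptor gene Kdr (0.51) rose and Lyz2 (-0.16) and Stab1 (-0.23) fell. The direction of the macrophage list in the test was up while its median was -0.02. The cell cycle call was lost without hAMSC 15 (adjusted p = 0.0821), the unfolded protein call without hAMSC 7 (0.239) or vehicle 17 (0.285), and the immediate early call without hAMSC 7 (0.144), vehicle 18 (0.277) or vehicle 20 (0.124). With sample quality weights the unfolded protein (adjusted p = 0.0659) and immediate early (0.0557) calls were lost, and with a mean of at least 5 CPM the cell cycle call (0.0562), its median going from 0.14 to 0.08.

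**Figure D4:**
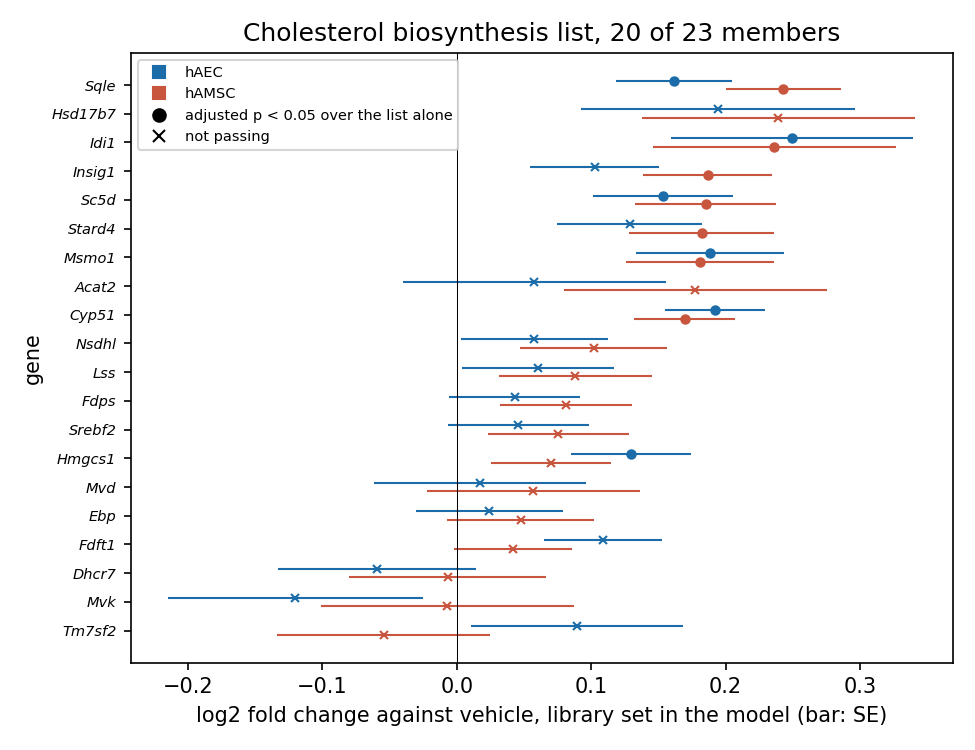
Log2 fold change against vehicle (horizontal, with SE bars) of 20 of the 23 measured cholesterol biosynthesis genes with the library set in the model, for hAEC and hAMSC. Circles mark the 6 genes drawn with hAEC and the 7 with hAMSC that passed when adjusted over the list alone, and crosses the others.

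Between hAEC and hAMSC, the clearest difference was in endothelial markers, which were lower with hAEC. Of 13 markers 12 were below 0, with a median of -0.30, and the list was called down (camera with Benjamini-Hochberg, adjusted p = 3.24e-06; adjusted p = 0.298 with an estimated correlation), in every fit that left out 1 library. Stab2 (-1.60), Kdr (-0.55) and Vwf (-0.40), of sinusoidal, growth factor receptor and clotting function, had its smallest p-values, none of which passed. In the higher-numbered set the marker level was 3.75 and 3.49 log2 CPM in hAMSC 15 and 16, above hAEC 11 and 12 (2.90 and 2.503) and vehicle 19 and 20 (2.92 and 2.84). In the lower-numbered set it was 3.75 and 3.95 in hAEC 3 and 4 and 3.97 and 4.204 in hAMSC 7 and 8. Without hAEC 12 the list median on camera's scale went from -0.40 to -0.20 (adjusted p = 0.00915), with a mean of at least 5 CPM to -0.25 (0.00358) and with sample quality weights to -0.27 (0.0178). The 21 other lists had adjusted p-values of 0.17 or more. Arhgef40 (0.29), Rabl2a (0.35), the amino acid transporter gene Slc1a4 (0.22), Syt11 (0.21) and Fmnl3 (0.19) were higher among the genes of smallest p. The glycosyltransferase gene Galnt6 (-0.19), Cd163 (-0.47), St3gal4 (-0.23), Tp53i11 (-0.18) and Tgfbr3 (-0.80) were lower. All 10 had an adjusted p of 1 by edgeR quasi-likelihood with Benjamini-Hochberg. That test called 0 genes, with 80 at an unadjusted p under 0.05. As for hAEC against vehicle, the difference between the sets lay in the residual spread, so fewer than 677 are expected with no effect. Limma voom called 0 and DESeq2 3 (LOC103694380, Galnt6 and Arhgef40, the first named after its value was seen). The number of lists called, 1 with all libraries, was 6 without hAEC 11, 4 without hAEC 12, 5 without hAMSC 7, 6 without hAMSC 8 and 2 without hAMSC 15. Here too, leaving out 1 library left the sets unequal in its group, with the set not in the model.

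With the library set in the model, 3 genes were lower with hAEC than with hAMSC. Vcan differed by -0.45 (SE 0.06; sets -0.54 and -0.33; adjusted p = 0.0176) and Pcsk1 by -0.32 (SE 0.04; sets -0.28 and -0.38; adjusted p = 0.0176), by edgeR quasi-likelihood with Benjamini-Hochberg. Fcgr2b (ENSRNOG00000046452), the inhibitory receptor for immunoglobulin G, differed by -0.35 (SE 0.05; sets -0.19 and -0.50; adjusted p = 0.042) by edgeR quasi-likelihood with Benjamini-Hochberg. Each was higher with hAMSC than with vehicle as well. With the endothelial marker level as a further covariate 0 genes were called: Vcan was at -0.55 (SE 0.08; adjusted p = 0.0912), Pcsk1 at -0.30 (SE 0.06; adjusted p = 0.337) and Fcgr2b at -0.19 (SE 0.06; adjusted p = 0.593). A fit that is not robust called 0 as well. Endothelial markers were again lower with hAEC (camera with Benjamini-Hochberg, adjusted p = 2.54e-05; adjusted p = 0.683 with an estimated correlation), with Kdr (-0.61) and Stab2 (-2.04) passing over the list alone. NF-kB targets were lower (adjusted p = 0.0296; adjusted p = 0.742 with an estimated correlation). Amino acid and unfolded protein genes were higher with hAEC (adjusted p = 0.00793; adjusted p = 0.577 with an estimated correlation), where Atf4, Trib3, Asns, Chac1, Sesn2, Phgdh and Mthfd2 passed over the list alone while the list median was 0.00. The p53 target list (adjusted p = 0.00565; adjusted p = 0.577 with an estimated correlation) and NRF2 genes (adjusted p = 0.0296; adjusted p = 0.742 with an estimated correlation) were higher with hAEC, with Nqo1 (0.12) and Hmox1 (0.14) passing over the list alone. The cholesterol list did not pass this test (adjusted p = 0.251), nor did the 16 other lists. Of 13539 genes 862 were at an unadjusted p under 0.05, where 677 are expected by chance. Limma voom called 2 genes (Pcsk1 and Vcan) and DESeq2 80, and the lower-numbered set alone called 1 (Vcan) and the higher-numbered set 58. Of these 58, 57 were measured in the lower-numbered set, and 46 had the same direction there (7 of 10 rises, 39 of 47 falls). Vcan had the same direction in the higher-numbered set. Genes are not independent replicates, and whether these counts exceed chance was not tested. None of the 3 genes was called without hAEC 3, hAEC 4, hAMSC 8 or hAMSC 15, and 1 gene outside the 3, higher with hAEC, was called without hAEC 4. Of the 3, 1 was called without hAEC 12 and 1 without hAMSC 16, and without hAMSC 7 the 3 were among 50 called, 17 of them higher with hAEC. Without hAEC 4, 1 list was called, that of endothelial markers, and the p53 (adjusted p = 0.0696), unfolded protein (0.0696), NRF2 (0.165) and NF-kB (0.112) calls were lost. The NF-kB call was lost also without hAEC 3 (adjusted p = 0.188), hAMSC 8 (0.591) or hAMSC 15 (0.151), or with a mean of at least 5 CPM (0.0667), the unfolded protein call without hAMSC 7 (0.167), the p53 call without hAMSC 7 (0.104) and the NRF2 call without hAMSC 8 (0.336) or 16 (0.263).

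By edgeR over all 12 libraries the 2 co-cultures had no called gene in common, since it called none for hAEC; with the set in the model DESeq2 called 2 for hAEC, Trpc6 and Cyp51. Of the 32 genes that changed with hAMSC, 30 had the same sign with hAEC, and the median ratio of the hAEC to the hAMSC log2 fold change was 0.335. Simulations in which shared vehicle libraries and the choice of genes act alone gave values of this size. In 20 simulations of unchanged groups, a mean of 30.2 of the 32 genes of smallest p for hAMSC had the same sign with hAEC. Their median ratio was 0.479. With the set in the model, these simulations had a larger covariance over all tested genes than the data (0.0563 against 0.0278), so they do not match the data in spread. When the 32 genes of smallest p were chosen against 2 vehicle libraries and hAEC was set against the other 2, 22 to 29 had the same sign. With libraries split in this way, a mean of 54.7% of all 13539 genes had the same sign. Vehicle libraries are not shared in these counts, so sharing does not account for them. Whether 22 to 29 exceeds chance was not tested. Fads1 (0.30 with hAEC, 0.37 with hAMSC), Man1a1, a Golgi mannosidase gene named after its values were seen (0.20 and 0.25), and Cd200r1 (0.25 and 0.39) were among the genes with the closest values. Fcgr2b (0.00 and 0.35), Vcan (0.01 and 0.46) and Gda (0.00 and 0.38) had hAEC values near 0. Over all 12 libraries with the set in the model, edgeR's direct test of hAEC against hAMSC called Vcan, Pcsk1 and Fcgr2b. Across all 13539 genes, which are not independent replicates, the 2 log2 fold changes correlated at r = 0.452. Unchanged groups set against the same vehicle libraries gave a mean of 0.493 in 20 simulations, and split vehicle libraries gave a mean of -0.0488. The covariance was 0.0272 against a simulated 0.0589, a difference of -0.0317. Among the 9903 genes with a mean of at least 5 CPM the covariance was 0.00908 against a simulated 0.0115, a difference of -0.00237. There r was 0.61 against a simulated mean of 0.466 (highest 0.715), and split vehicle libraries gave r = 0.147. With the group alone in the model the overlap of calls was 0 as observed, with unchanged groups, with split vehicle libraries and for independent lists.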

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

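The tests of the macrophage transcripts, of the library sets, of human RNA and of endothelial cells were chosen only after the results were seen. So was every fit with the library set in the model. The counts over other splits of the libraries were fixed before those counts were seen, with 2 exceptions. The limit to splits with 2 libraries of each set on both sides and the count for the cholesterol list alone were set afterwards.

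All 12 libraries carried the macrophage list above the matrix list, although the labels name stellate cells. RNA of the human cells in the inserts is argued against by a difference in macrophage marker level between co-cultured and vehicle libraries of -0.00541 log2 units. That value averages small shifts of opposite sign. Co-cultured libraries lay at 7.883 to 7.956 against 7.959 and 8.039 in vehicle of the lower-numbered set. In the higher-numbered set they lay at 8.765 to 8.844 against 8.754 and 8.755. A minor share of macrophages among stellate cells is argued against by the lowest ratio of the medians of tested members, 253 in vehicle 17. Isolates made mostly of macrophages and libraries labelled for another cell type cannot be told apart, since both put the macrophage list first in 12 of 12 libraries, and gradient centrifugation selects by density and not by a marker. No biological explanation was tested, since no group of the design differs in cell type.

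The libraries lay in 2 sets on a component with 73.5% of the variance. A different share of macrophages, as the whole difference, is argued against by macrophage markers that moved in opposite directions between the sets, with a span of 6.002 log2 units from Cd14 to Adgre1. As a part of the difference it stays open, because 7 markers were over 1 log2 unit higher in the higher-numbered set and only 2, Marco and Cd14, in the lower-numbered one, where the test asked for 3. Animals of different sex are argued against by the Y-linked gene Kdm5d, at 42.6 CPM or more in every library. Separate isolations, animals or days may be the source and stay open because the labels name none, and no biological explanation was tested, since the sets cross all groups.

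For the 32 genes that changed with hAMSC with the set in the model, RNA of the human cells stays open. The 28 tested matrix genes, which mesenchymal cells express strongly and whose median log2 fold change was -0.12, lay near the floor at a median of 2.23 CPM and did not pass (adjusted p = 0.224 by camera). For endothelial cells in hAMSC 15 and 16 as the whole cause, the fold changes with the endothelial level as a covariate were compared with those without it. Their median ratio was 0.929 (quartiles 0.826 and 1.02), and 17 of the 32 genes were still called. The 32 genes were called for a change common to both sets, while only in the higher-numbered set did endothelial levels part hAMSC from vehicle. The ratio was thus partly fixed by the choice of genes, and this test does not settle the question. The 18 splits with 2 libraries of each set on both sides are too few for a share under 5%: 1 of them, the real one, gave 32 genes, and the highest other gave 31, with hAMSC 7, 8 and 16 and vehicle 20 on one side. Co-culture with hAMSC, which the design names, and a difference between cultures that goes with the group by chance stay open as untested.

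With the group alone in the model edgeR called 0 genes in each of the 3 comparisons (DESeq2 1 for hAEC against vehicle and 3 for hAEC against hAMSC), a count that any split reaches (35 of 35 splits), so the splits do not test it. The highest counts, 8068 for hAEC and vehicle, 7922 for hAMSC and vehicle and 7826 for hAEC and hAMSC, came from the split that follows the library sets, which is a structure of the libraries and not of the groups. For gene lists with the group alone, 29 of 35 splits gave as many as the 1 called for hAEC against vehicle (highest other 10), 22 of 35 as many as the 4 for hAMSC against vehicle (highest other 8) and 33 of 35 as many as the 1 for hAEC against hAMSC (highest other 10), so chance was not excluded. The 10 for hAEC and vehicle came from the split that follows the sets. Among the 18 splits with 2 libraries of each set on both sides, 12 gave as many for hAEC against vehicle (highest other 2), 6 for hAMSC against vehicle (highest other 8) and 16 for hAEC against hAMSC (highest other 2). With the set in the model, the 18 splits like the real one are too few for a share under 5%. In genes the real split gave 3 for hAEC against hAMSC (highest other 2; 1 of 18 splits as large) and 0 for hAEC against vehicle (highest other 1), which all 18 reach. In lists it gave 6 for hAEC (highest other 6; 3 of 18 splits), 6 for hAMSC (highest other 7; 4 of 18 splits) and 5 for their difference (highest other 10; 6 of 18 splits). The cholesterol list was picked out for such a count after its result was seen, so a high value in the real split is partly due to that choice. By the negative log10 of its p, the real split gave 10.2 for hAEC (highest other 5.18, 1 of 18 splits). For hAMSC it gave 11.2 (highest other 13.3, 2 of 18 splits).

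In 192 groups of 4 libraries checked for a library far from the others, 2 were found. Each group held 2 libraries of each set. For items in which the sets lie far apart, that gap fills most of the range, and the check does not flag a single library. The chance rate of about 5% holds for 4 libraries with no such gap, so the count of 2 is not compared with it. The mean log2 CPM of the matrix list was 1.82 in hAMSC 7 and 2.13 to 2.14 in the other hAMSC libraries. Tgfb1 was at 283 CPM in vehicle 20 and at 251 to 254 CPM in the other vehicle libraries. For 27 genes the hAMSC effect differed between the library sets by an interaction test (edgeR quasi-likelihood with Benjamini-Hochberg), where hAEC had 0. At an unadjusted p under 0.05 by edgeR alone there were 1358 for hAMSC and 731 for hAEC, where 677 are expected by chance.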

How the results depend on the processing

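Fits with the library set and with the endothelial covariate, and marker levels permuted within the sets, were chosen after the data were seen; the others were planned. In the group-only fit, settings other than leaving out 1 library kept 3518 values for named genes on their side of the threshold. Another 16 came to pass. With the set in the model 2514 kept their side, 53 came to pass and 64 no longer passed. With 1 library left out, 1952 kept their side in the group-only fit. With the set in the model and 1 library left out, 1885 did so, 15 came to pass and 92 no longer passed. Direction was not compared for values that passed in neither fit. No gene passed in the main group-only fit, so 3518 and 1952 count values that passed in neither. No scaling moved the median log2 fold change by more than 0.02. The depth of 27382724 to 34922211 counts limits genes of few CPM, such as Acta2 and Col1a1.

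With the group alone, DESeq2 called 1 gene for hAEC against vehicle and 3 for hAEC against hAMSC, and 1 surrogate variable gave 14 for hAMSC against vehicle. That variable, a planned setting, followed the library sets. It lay between -0.3002 and -0.2772 in the lower-numbered libraries and between 0.2566 and 0.3027 in the higher-numbered ones. The library set as a covariate gave 32 for hAMSC against vehicle and 3 for hAEC against hAMSC. The lower-numbered set alone gave 1, 86 and 1, and the higher-numbered set alone 6, 94 and 58, for hAEC against vehicle, hAMSC against vehicle and hAEC against hAMSC. Leaving out 1 library gave 0 to 0 in each. With the set in the model, hAEC against vehicle gave 2 by DESeq2 and 10 with the 2 groups alone (0 to 0 with 1 library left out). hAMSC against vehicle gave 52 with no filter, 155 by DESeq2, 12 when not robust, 9 with the 2 groups alone, 93 with the endothelial covariate, and 8 to 153 with 1 library left out. hAEC against hAMSC gave 26 with no filter, 80 by DESeq2, 28 with quality weights, 0 when not robust, 0 with the endothelial covariate, and 0 to 50 with 1 library left out.

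For gene lists with the group alone, an estimated correlation and fry each gave 0 in all 3 comparisons. A mean of at least 5 CPM gave 2 for hAMSC, quality weights 2 for hAMSC and 6 for hAEC against hAMSC, and the set as a covariate 6 for hAEC and 5 for hAEC against hAMSC. Leaving out 1 library gave 0 to 6, 0 to 11 and 1 to 6. With the set in the model, an estimated correlation gave 0, 0 and 0, fry 1 (cholesterol biosynthesis), 3 and 0, and leaving out 1 library 5 to 9, 5 to 9 and 1 to 7. With quality weights and the group alone, the cholesterol list reversed with hAEC (median -0.0185 on the log2 scale, adjusted p = 0.912 by camera), and with hAMSC it no longer passed (median -0.0168, adjusted p = 0.798). The overlap of calls stayed at 0, which was fixed in each fit where hAEC or hAMSC had no call. The covariance of 0.0272 became -0.00653 with split vehicle libraries and 0.00909 with a mean of at least 5 CPM. Marker levels gave 0 by library size and 0 within the sets. Within the sets that count was fixed, because the smallest possible exact permutation p of 0.0556 lies above the threshold. No paired analysis was possible because the groups share no sample numbers. The cause was not tested for any of these, except that leaving out libraries, the sets alone and the 2 groups alone use fewer libraries, and the 5 CPM minimum fewer genes. With the group alone in the model, leaving out 1 library also leaves the 2 sets unequal in its group. That moves lists whose level differs between the sets.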

Other observations

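The genes described here were chosen after their values were seen, as was the test by set.

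For 27 genes the hAMSC effect differed between the library sets. Clec14a, a lectin of endothelial cells, averaged 17.04 CPM in the higher-numbered hAMSC libraries (n = 2), against 5.68 CPM in vehicle and 6.45 CPM with hAEC of that set, while in the lower-numbered set it was at 29.3 CPM with hAMSC and 31.4 CPM with vehicle (adjusted p of the interaction 0.0173, edgeR quasi-likelihood with Benjamini-Hochberg). Esam, an endothelial adhesion molecule, was at 10.3 against 5.40 CPM in the higher-numbered set, Adgrl4 at 11.8 against 5.40 CPM, and the endosomal gene Ehd3 at 18.8 against 8.37 CPM. The potassium channel gene Kcnj8, of pericytes, was at 2.63 against 0.332 CPM and the imprinted gene Mest at 5.78 against 1.05 CPM. The vasoconstrictor gene Edn1 was at 16.8 CPM in hAMSC 15 and 13.7 CPM in hAMSC 16, and between 6.51 and 8.79 CPM in the other libraries.

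The ranges of the 2 sets were also apart for Mrc1, Arg1, Mki67 and Mmp9. The mannose receptor gene Mrc1 lay between 311 and 358 CPM in the lower-numbered set and between 1374 and 1490 CPM in the higher-numbered one, and the arginase gene Arg1 between 18.4 and 28.2 and between 1.13 and 2.02 CPM. The proliferation marker Mki67 lay between 9.99 and 13.6 and between 42.8 and 61.6 CPM. The metalloprotease gene Mmp9 lay between 412 and 548 CPM in the lower-numbered set and between 70.4 and 98.5 CPM in the higher-numbered one.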
